A study of Rattus norvegicus with 3 samples.

How the data were processed

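RNA was measured in 3 libraries of untreated, cultured Schwann cell precursors, the early glia of the peripheral nerve, grown from dorsal root ganglia of embryonic wild-type rats. The libraries were made with a stranded, poly(A)-selecting kit for Illumina sequencing, per the labels' protocols. All 3 libraries form 1 group, and no second group was analysed here. The labels do not say whether the 3 libraries came from separate cultures, so each p-value measures only the spread between these libraries, which may be technical.

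The authors' table holds raw counts per gene, gene lengths, values per kilobase and TPM (counts divided by gene length and scaled to a total of 1000000 in each library). STAR 2.5.2b, Subread and the genome build rn6 are named in the submitters' processing notes. The gene annotation, the strand setting and the handling of reads with several matches are not given in the sources used here, so levels of genes that overlap on opposite strands, and of genes with near-identical copies, are uncertain. Deposited count columns were matched to libraries by the library title in the column name, and the deposited TPM columns by the number in their names, with values equal to those made from the matching count column. TPM recomputed from the deposited counts and lengths differed from the deposited TPM by at most 0.0005 TPM in each library, within a tolerance of 0.001. Counts over length (another kind of column the authors deposited) were not used further, and 6 columns of per-library totals were not used. The 2 rows without a gene name were left out. The table lists 17337 genes, of which 26 have symbols changed into dates and none is mitochondrially encoded. Gene symbols were taken from the table, and NCBI gene identifiers were looked up in a table of the GRCr8 assembly, which was used for names alone. Of the identifiers, 16864 matched, and 352 rows had none.

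Total counts were 15309526, 14139074 and 14162738 in replicates 1, 2 and 3. A count of 3 in a gene of median length corresponds to 0.216, 0.232 and 0.232 TPM in those libraries. Such floors and counting intervals cover counting error only, since reads carry no molecular identifiers. A chi-square test over genes with at least 20 counts in a pair of libraries gave a statistic per degree of freedom of 2.35, 1.87 and 1.67 for the 3 pairs, where sampling noise alone gives about 1, so no pair was treated as 1 library deposited under a pair of names. This does not show that the libraries came from separate cultures. The common biological coefficient of variation from edgeR 4.0.16 was 2.73%, and edgeR was used for nothing else.

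The lists, pairs, tests and most alternatives were fixed before the data were examined. A gene was called detected at 1 TPM or more in each library. Each gene with a count in at least 1 library was tested with limma 3.58.1 (R 4.3.3), as log2(TPM + 1) against the value at 1 TPM, with a moderated one-sample test with trend, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The pseudocount of 1 makes differences of low genes look smaller. For 35 lists (16 of cell type markers and 19 of gene function), the median TPM of the measured members was taken in each library. The median of the mean log2(TPM + 1) was placed among 10000 random lists of the same size drawn from genes with a count plus the list's members, as a description with no p-value. The precursor list was set against 15 other cell type lists as the difference of mean log2(TPM + 1) per library, with an exact sign-flip permutation test whose smallest p with 3 libraries is 0.25. Gene pairs were tested with limma on log2 ratios of TPM, with 0.1 TPM added to each gene. Of 52 fixed pairs, 49 were measured. Spread between libraries was counted as genes with a mean TPM of 10 or more whose highest library was over 2 times the lowest. Of 445 list and pair symbols, 414 were matched, 3 of them by identifier and 1 by a synonym, and 31 were not used here.

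The limma steps were tested on simulated data. In the simulation of the test against 1 TPM, run on 13101 genes, 50 of 50 genes were called below at 0.25 and at 0.5 TPM, 49 of 50 above at 2 TPM, 50 of 50 above at 4 TPM, and 4 of 50 either way at a true level of 1 TPM. In the simulation of gene pairs, run on 200 pairs, 50 of 50 were called at log2 ratios of 0.5, 1 and 2, and 3 of 50 at a true ratio of 0. The simulated pairs were drawn from genes above a minimum length and mean TPM. They do not cover pairs with a member near the floor, such as Hes5, Erbb4 or Bmpr1b.

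Named genes are the members of the lists (the 6 with the highest mean TPM first, and members under 1 TPM in every library), members of the pairs that passed (largest ratio first), the 20 genes with the highest mean TPM apart from ribosomal protein and mitochondrial genes, and up to 10 genes with the largest ratio between libraries. Some genes that this rule names are not reported here. Alternatives were other detection levels, pseudocounts, filters, variance estimates, backgrounds and list statistics, TPM rescaled without ribosomal protein genes, median-of-ratios factors, and each library left out in turn. After the data were seen, alternatives were added without genes listed at 2 places in the genome (genes with at least 4 exons whose listed exons split into 2 sets sharing at least 0.5 of their exon lengths), without genes under 200 bases, and with at least 100 counts on average. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.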

Results

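Gene expression was measured by RNA sequencing in 3 libraries of cultured Schwann cell precursors from embryonic rat dorsal root ganglia, with 14139074 to 15309526 counts per library. The labels name 1 untreated group, so the data give levels of genes within these cultures, whose cell composition was not measured. Values are TPM ± SD over the libraries (n = 3), except that log2 ratios of gene pairs are given ± SE from limma. In total, 10513 of 17337 genes were at 1 TPM or more in each library, and 3992 had no count. By limma against 1 TPM, 10458 genes were above and 2374 below at a Benjamini-Hochberg adjusted p under 0.05, and 513 of the 13345 tested passed in neither direction. The number below depends on how many near-silent genes are tested, being 6235 with no filter on low values and 1372 with a mean of at least 0.1 TPM required.

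The most abundant transcript apart from ribosomal protein genes was Vim, encoding the intermediate filament vimentin, at 12837 ± 380 TPM. It was followed by the translation factor Eef1a1 at 9233 ± 144 and the matrix glycoprotein gene Sparc at 7338 ± 53.5. Among the 20 highest were the actin gene Actb at 4377 ± 95.1, Tmsb4x at 3908 ± 22.3, Tmsb10 at 3803 ± 87.4 and Cfl1 at 2567 ± 33.0. Collagen and its chaperone were also present, with Col1a1 at 3842 ± 64.6 and Serpinh1 at 3612 ± 19.8. Lipid-related genes among the 20 were the desaturase Scd2 at 4142 ± 50.7, the acyl-CoA binding protein gene Dbi at 3166 ± 40.4 and the lipocalin Apod at 2985 ± 45.7. Among the 20 were also Tpt1, Lgals1, Fth1, Mgp, Cd63, Cadm4 and S100a11, at 2552 to 4400 TPM, where Cadm4 encodes a glial adhesion molecule and reached 2581 ± 95.6.

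The first question was how far the libraries express genes of the named cell type. All 13 genes of the Schwann cell precursor list were above 1 TPM by limma, and 9 were at 100 TPM or more in each library. Abundant members were the endothelin receptor Ednrb at 1414 ± 16.7 TPM, the neurotrophin receptor Ngfr at 655 ± 20.7, the glial transcription factor Sox10 at 612 ± 26.0 and the neuregulin receptor Erbb3 at 581 ± 14.3. Dhh, the hedgehog ligand of Schwann cells, was at 316 ± 10.9 TPM, and the cadherins Cdh19 and Cdh2 were at 247 ± 9.13 and 195 ± 5.80. Lower members were Itga4 at 66.1 ± 3.13, Gap43 at 58.3 ± 2.31, Tfap2a at 16.7 ± 0.633 and Fabp7, a lipid-binding protein of early glia, at 3.32 ± 1.31 TPM. The list's median was 316 ± 10.9 TPM at percentile 100 among random lists of the same size. In rn6 coordinates, Sox10 (NCBI gene 29361) lies on the minus strand of chromosome 7 from 120393254 to 120403523 with 5 listed exons, and Erbb3 (29496) on the same strand and chromosome from 2991016 to 3010312 with 28.

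Markers of neighbouring stages of the lineage were present as well. All 9 genes of the immature Schwann cell list were above 1 TPM, led by Vim, the calcium-binding protein gene S100b at 2061 ± 14.9, Jun at 414 ± 31, Sox2 at 263 ± 11.8 and the adhesion molecule Ncam1 at 221 ± 6.16, with a median of 221 ± 6.16 TPM at percentile 99.97. Of the myelinating Schwann cell list, 12 of 13 genes were above 1 TPM, but the levels were uneven. Pmp22 was at 628 ± 18.9, Pmp2 at 262 ± 13.2, Pllp at 90.5 ± 3.70, Ugt8 at 63.0 ± 1.74 and Egr2, the transcription factor that drives myelination, at 52.3 ± 2.45, whereas Mbp was at 18.7 ± 1.08 and Mag at 0.21 ± 0.0878, below 1 TPM. The median of that list was 18.7 ± 1.08 TPM. Its percentile depends on the choice of statistic and background, being 41.63 by the median, 76.31 by the mean log2 over members and 10 by the median against detected genes. Of the neural crest list, 10 of 12 measured genes were above 1 TPM, led by Ets1 at 77.1 ± 3.69, Zic1 at 65.5 ± 6.24, Snai2 at 52.6 ± 1.80, Snai1 at 37.1 ± 1.88 and Twist1 at 35.3 ± 1.31. In the same list Sox9 was at 2.52 ± 0.0676, Msx1 at 0.462 ± 0.216 and Pax7 had no count. The median of the neural crest list lay at percentile 41.48, or 29.62 by the mean log2 over members and 9.42 against detected genes.

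**Figure D1:**
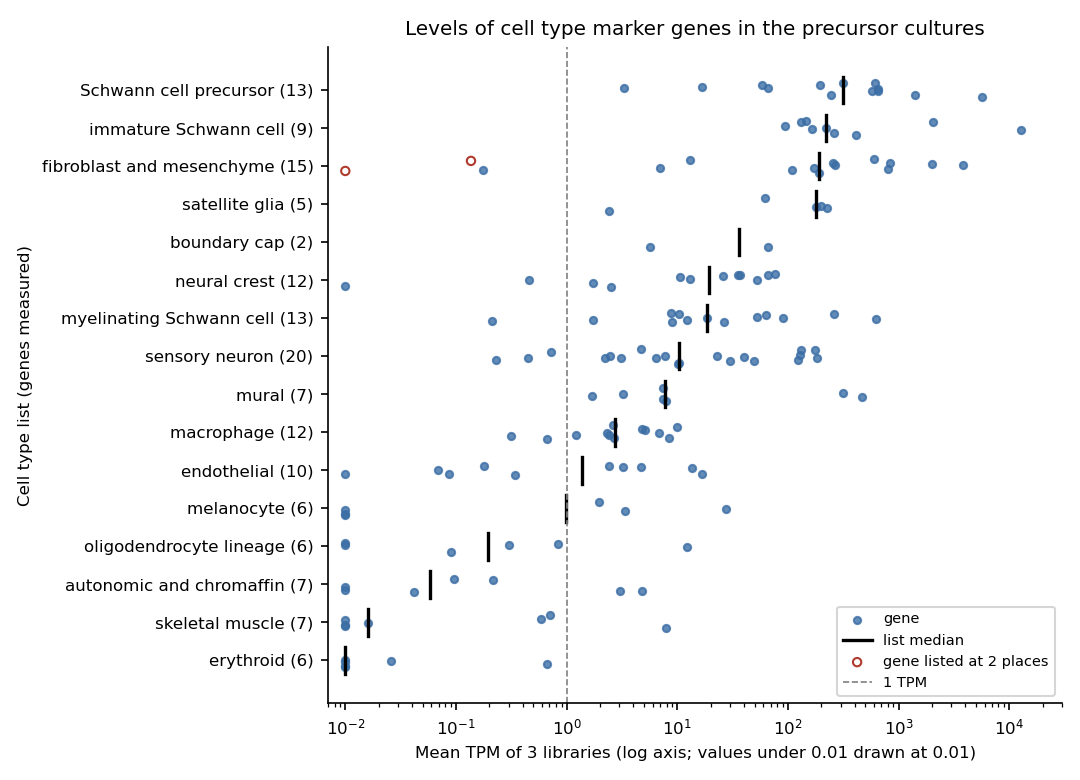
Mean TPM of 3 libraries (log axis) of each measured gene of the 16 cell type lists, with 1 point per gene, the list median as a bar and 1 TPM as a dashed line; red circles are genes listed at 2 places in the genome. The precursor list has the highest median, 316 TPM, and the erythroid list the lowest, 0 TPM.

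The next comparison set the precursor list against markers of other cells that a ganglion preparation could hold, in the same libraries. The mean log2(TPM + 1) of the precursor list was higher than that of 14 of the 15 other lists in 3 of 3 libraries. The difference was 3.90 ± 0.06 (SD, n = 3) against sensory neurons, 4.16 ± 0.03 against neural crest, 3.23 ± 0.03 against myelinating Schwann cells, 3.46 ± 0.12 against boundary cap cells and 1.72 ± 0.05 against satellite glia. It was 5.85 ± 0.11 against macrophages, 6.33 ± 0.07 against endothelium and 3.58 ± 0.10 against mural cells. Against melanocytes, oligodendrocyte lineage, autonomic cells, skeletal muscle and erythroid cells it was between 6.44 and 7.73. The immature Schwann cell list was 1.67-fold higher than the precursor list (difference -0.74 ± 0.04), but by the median over members the sign turned, to 0.51. The median over members also moved other differences by over 1.5-fold, to 0.83 for satellite glia, 4.01 for myelinating Schwann cells, 4.81 for sensory neurons, 5.19 for mural cells, 7.22 for endothelium and 7.53 to 8.28 for melanocytes, oligodendrocyte lineage, autonomic cells and skeletal muscle. With a pseudocount of 0.1 the difference was 7.66 for endothelium and 8.21 to 10.63 for the 5 lists with the lowest levels. For each list the exact sign-flip permutation test gave p = 0.25, the smallest that 3 libraries allow, so none of these differences can pass a threshold of 0.05.

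Outside the Schwann cell lists, the fibroblast list had the highest median. Col1a1 and Col3a1 were at 3842 ± 64.6 and 2009 ± 34.3 TPM, the proteoglycans Dcn and Lum at 842 ± 20.3 and 602 ± 16.2, Postn at 800.4 ± 35 and the growth factor receptor Pdgfra at 267 ± 1.71. Of the 15 fibroblast genes, 12 were above 1 TPM by limma, and the list's median was 192 ± 2.99 TPM, at percentile 100. Without Col1a2 and Ogn the median was 254 TPM, between the 221 TPM of the immature Schwann cell list and the 316 TPM of the precursor list. Col1a2 at 0.137 ± 0.0393 and Ogn with no count belong to genes listed at 2 places in the genome. Of such genes 89.4% were below 1 TPM, against 26.8% of the other genes with 4 or more exons. Without the genes listed at 2 places the precursor list exceeded the fibroblast list by 0.44 ± 0.02 in place of 1.42 ± 0.02 log2 units. By the median over all members, with those genes kept, the difference was 0.72. The satellite glia list had a median of 178 ± 0.239 TPM (percentile 99.49), with Apoe at 225 ± 4.05, the gap junction gene Gja1 at 198 ± 3.53 and Glul, glutamine synthetase, at 178 ± 0.239. In the mural list Tagln at 466 ± 13.0 and Acta2 at 317 ± 10.9, both genes of contractile cells, stood far above the other 5 members, which were at most 7.90 TPM.

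Of the 20 measured sensory neuron genes, 17 were above and 3 below 1 TPM by limma. The median of this list lay at percentile 12.89, or 39.93 by the mean log2 over members and 0.15 against detected genes. The neuronal tubulin Tubb3 at 185 ± 5.76, the intermediate filament genes Prph at 176 ± 5.71, Nefl at 130.1 ± 3.68 and Nefm at 129 ± 2.24, and Stmn2 at 124 ± 4.68 TPM were the highest, followed by the neuropeptide gene Tac1 at 49.3 ± 1.43. Ntrk2, Dcx and Runx3 were below 1 TPM in every library. Macrophage genes were low, led by Lyz2 at 9.85 ± 0.463 and Tyrobp at 8.35 ± 1.32, with Ptprc at 0.316 ± 0.0756. Endothelial genes were led by Cdh5 at 16.6 ± 1.03 and Emcn at 13.7 ± 0.836, and Pecam1 was at 0.0693 ± 0.0695. None of the erythroid genes reached 1 TPM in each library, and of the melanocyte list Kit was at 27.8 ± 2.39 while Tyr, Mlana and Slc45a2 had no count. The muscle regulators Myod1, Myog and Myf5 and the autonomic regulators Phox2a and Hand2 also had no count, Myrf was the highest of the oligodendrocyte list at 12.2 ± 0.402, and Hey2 at 66.2 ± 0.778 and Wif1 at 5.63 ± 0.789 were the boundary cap genes measured.

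The functional lists asked which pathways' genes were expressed in these cultures. Of the 13345 genes tested, all with a count, 10458 were above 1 TPM, out of 17337 genes listed. The list counts include members with no count, as the 17337 do and the 13345 do not. Counts near either share do not set a list of either kind apart. Matrix and lipid genes stood out. In the basal lamina and matrix list all 13 measured genes were above 1 TPM, with a median of 531 ± 10.5 TPM (percentile 100). Beside Sparc, fibronectin Fn1 was at 932 ± 42.6, dystroglycan Dag1 at 821 ± 6.69, Col4a1 at 776 ± 6.4 and the laminin genes Lamc1 and Lama4 at 636 ± 8.56 and 531 ± 10.5. All 17 cholesterol and lipid synthesis genes were above 1 TPM and 14 were at 100 TPM or more in each library, led by Fdps at 905 ± 26.7, Hmgcs1 at 627 ± 12.9 and Cyp51 at 483 ± 11.1, with a median of 207 ± 2.13 (percentile 100). All 11 measured integrin genes were above 1 TPM, with Itgb1 at 964 ± 25.2, Itgb8 at 341 ± 14.4 and the laminin receptor subunit Itga7 at 327 ± 0.469. Of the 11 measured cadherin genes 7 were above 1 TPM, including Cdh11 at 238 ± 9.42, while Cdh7 and Cdh8 had no count.

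Proliferation genes were expressed throughout. All 23 cell cycle genes were above 1 TPM, with the G1 cyclins Ccnd1 at 498 ± 2.60 and Ccnd3 at 386 ± 12.8, the replication clamp Pcna at 187 ± 2.61, Cdk1 at 125 ± 3.39 and Top2a at 80.8 ± 4.71. All 7 measured inhibitors were also above 1 TPM, led by Cdkn1b at 211 ± 6.33 and Cdkn2b at 84.7 ± 4.54. All 32 measured glial and crest transcription factors were above 1 TPM, including Zeb2 at 283 ± 8.58, Sox4 at 235 ± 10.3 and Pou3f1 at 147 ± 11.7, and so were all 18 measured chromatin regulators, with Hdac2 at 236 ± 4.26, Hdac1 at 199 ± 3.01 and Hdac5 at 141 ± 4.78. Of the 14 measured Hippo genes 13 were above 1 TPM, with Wwtr1 at 357 ± 3.99 and Tead1 at 224 ± 20. The medians of the cell cycle, transcription factor, chromatin and Hippo lists lay at percentiles 97.81, 96.76, 95.91 and 98.09, but at 87.43, 75.36, 81.72 and 92.38 when random lists were drawn from detected genes, so they are high against all genes with a count and not against detected genes.

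Of the 13 measured ERBB genes 6 were above and 3 below 1 TPM. Erbb3 was followed by Hbegf at 114 ± 4.82, Erbb2 at 96.0 ± 1.19, Btc at 87.8 ± 8.06 and Egfr at 21.4 ± 0.96, whereas Nrg1, the ligand of Erbb3, was at 1.16 ± 0.0341 and Ereg had no count. Nrg1 was chosen for mention after its value was seen. Of 18 Notch genes 14 were above 1 TPM, with Lfng at 159 ± 5.81, Notch1 at 125 ± 2.93 and Hey1 at 68.8 ± 6.66, and the target Hes5 had no count. The medians of the ERBB and Notch lists lay at percentiles 0.89 and 13.63, or 10.82 and 25.28 by the mean log2 over members. In the hedgehog list 10 of 11 genes were above 1 TPM, with the receptor Ptch1 at 216 ± 6.4 and the target Gli1 at 32.1 ± 0.355 TPM. The Wnt list had 18 of 21 above, with Ctnnb1 at 938 ± 19.9 and Fzd2 at 261 ± 11.7, and the TGF-beta and BMP list 18 of 21, with Id3 at 247 ± 6.72 and Tgfbr2 at 214 ± 4.5. In the latter Bmp2, Bmpr1b and Nog were below 1 TPM in every library. Dkk1 had no count but is listed at 2 places. Of 21 receptors for growth factors 20 were above 1 TPM, with Gfra1 at 642 ± 12.8 and Il6st at 216 ± 6.33, and among 18 growth and survival factors 16 were above, with Igf2 at 171 ± 5.98, Pdgfa at 102 ± 2.07 and Vegfa at 80.4 ± 3.90. In the repair Schwann cell list 11 of 12 genes were above 1 TPM, with Gfap at 165 ± 4.36, Runx2 at 58.1 ± 0.407 and Artn at 43.7 ± 0.908, while Olig1 was at 0.834 ± 0.204. The list medians lay at percentile 68.44 for hedgehog, 72.1 for Wnt and 44.1 for TGF-beta and BMP. They lay at 68.76 for growth factor receptors, 39.12 for growth and survival factors and 82.28 for repair genes. These percentiles also depend on the statistic and background. By the mean log2 over members they were 84.1, 56.48, 72.83, 98.48, 46.72 and 78.19, in the same order of lists. Against detected genes they were 38.04, 30.49, 6.56, 26.42, 5.29 and 55.17.

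Among immediate early and stress genes 10 of 12 were above 1 TPM, with Jund at 249 ± 23.9, Fos at 155 ± 12.3 and Ier2 at 105 ± 6.46, while Hspa1b was at 0.608 ± 0.0484. Of the 10 housekeeping genes 9 were above 1 TPM, including Rplp0 at 3066 ± 65.4, Ppia at 2166 ± 2.76 and Gapdh at 1858 ± 13.6. Hprt1 was at 0.309 ± 0.0973 TPM, and it too is listed at 2 places in the genome. For each of the 35 lists the numbers above and below 1 TPM adjusted over the list alone equalled those adjusted over all genes tested.

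**Figure D2:**
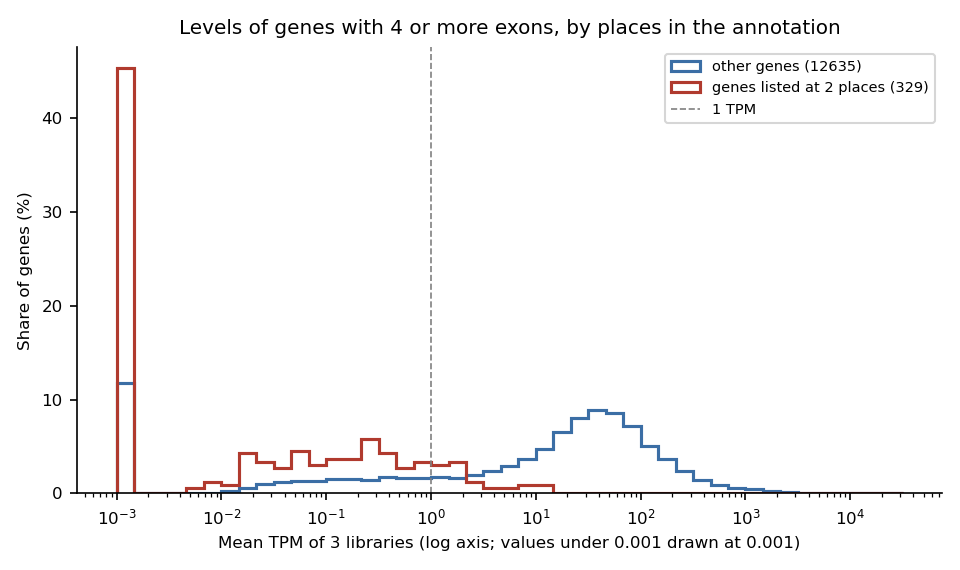
Share of genes (%) by mean TPM of 3 libraries (log axis) for 329 genes whose exons are listed at 2 places in the genome and for 12635 other genes with 4 or more exons; the dashed line marks 1 TPM. The genes listed at 2 places have a median of 0.0167 TPM and the others one of 18.6 TPM.

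Pairs of related genes were compared within libraries to ask which member dominates. Sox10 exceeded Sox9 by a log2 ratio of 7.87 ± 0.05 (SE), Sox8 by 5.99 ± 0.05 and Sox2 by 1.22 ± 0.04. Ngfr exceeded Ntrk2 by 9.65 ± 0.08 (8.58 with a pseudocount of 1), Ednrb exceeded Ednra by 5.27 ± 0.05 and Gfra1 exceeded Gfra3 by 5.40 ± 0.09. Among markers used to stage Schwann cells, S100b exceeded both Fabp7 (Fabp7 over S100b -9.30 ± 0.21) and Gap43 (Gap43 over S100b -5.14 ± 0.04), and Vim exceeded Gfap by 6.28 ± 0.04. Jun and Sox2, which oppose myelination, exceeded Egr2 by 2.98 ± 0.05 and 2.33 ± 0.04. All 49 measured pairs passed by limma with Benjamini-Hochberg adjustment, 42 with the first gene higher and 7 with the second, and the largest adjusted p was 0.0064.

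Erbb3 stood above Erbb2 by 2.60 ± 0.04, above Egfr by 4.76 ± 0.04 and above Erbb4, which had 6 counts over the 3 libraries. The ratio of mean TPM of Erbb3 to Erbb4 was 8261-fold with a 95% exact Poisson interval of 3795 to 22509 for counting error, and that of Bmpr1a to Bmpr1b, also with 6 counts, was 520-fold with an interval of 239 to 1417. These ratios have nothing added to the TPM, and the tested log2 ratios depend on the pseudocount. For Erbb3 to Erbb4 the log2 ratio was 11.76 ± 0.12 with 0.1 TPM added, or 3468-fold, and 9.09 with a pseudocount of 1. For Bmpr1a to Bmpr1b it was 8.66 ± 0.44, or 404-fold, with 6.37 at a pseudocount of 1 and 8.05 without replicate 2. Hes1 was at least 66.6-fold higher than Hes5, with Hes5 set at 3 counts in each library. Pairs with the second gene higher included Tgfbr1 to Tgfbr2 (log2 ratio -2.64 ± 0.05), Yap1 to Wwtr1 (-1.29 ± 0.04) and Itga6 to Itga7 (-1.27 ± 0.04). The smallest ratios were those of Cdh19 to Cdh2 (0.34 ± 0.04), Igf1r to Insr (0.26 ± 0.05) and Hdac1 to Hdac2 (-0.25 ± 0.04), and without replicate 3 their limma adjusted p became 0.0646, 0.231 and 0.215. The ratios were then 0.35, 0.22 and -0.23, but limma gave all 49 pairs a common SE of 0.181 in that setting. The rise in p therefore does not show that these pairs depend on replicate 3. A ratio of TPM between genes rests on the listed gene lengths and on equal recovery of reads from both genes, which was not measured.

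**Figure D3:**
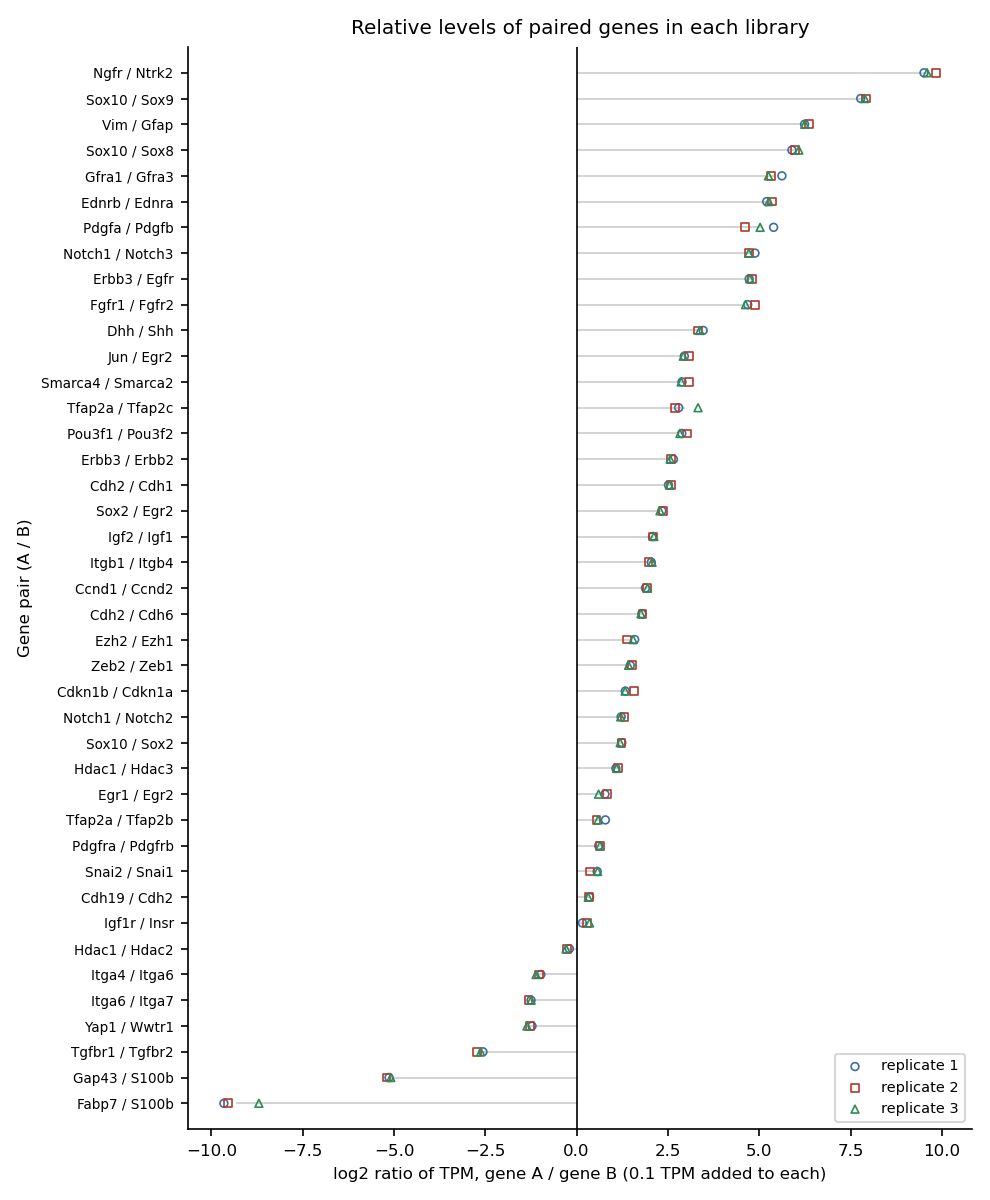
Log2 ratio of TPM between the genes of 41 of the 45 pairs with at least 30 counts in both genes (0.1 TPM added to each), with 1 symbol per library; the other 4 pairs include genes not reported here. The ratios run from -9.30 for Fabp7 over S100b to 9.65 for Ngfr over Ntrk2.

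Levels were close between libraries. Of 8372 genes with a mean of 10 TPM or more, 2 differed over 2-fold between the highest and the lowest library, and the median coefficient of variation was 3.84%. These genes were Rmrp, a noncoding RNA of 257 bases with 32 to 124 counts and a ratio of 3.87, and the microRNA gene Mir568 with 22 to 58 counts and a ratio of 2.45. Next came Mir27b at 1.95 and Mir7a-1 at 1.90, and the first protein-coding genes were Fam213b at 1.80 and Inafm1 at 1.71. At a ratio of 1.5, 19 genes differed, with replicate 1 the highest in 5, replicate 2 in 7 and replicate 3 in 7. The count was 200 at a mean of 1 TPM or more, 1 without replicate 1 and 0 among genes with at least 100 counts on average.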

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

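The alternatives without genes listed at 2 places, without genes under 200 bases and with at least 100 counts were chosen after seeing the data. No paired analysis was possible because the libraries form 1 group. The number of detected genes ranged from 9187 at 5 TPM to 10945 at 0.5 TPM, and genes above 1 TPM by limma from 10364 with no filter to 10463 without trend, with 10340 to 10468 when a library was left out. Genes below 1 TPM numbered 6235 with no filter and 1372 with a mean of at least 0.1 TPM required, since these choices set how many near-silent genes are tested. The lists at or above percentile 95 numbered 13, with 15 by mean log2 over members and 9 against detected genes. The precursor list exceeded 14 of the 15 others, and by the median over members its difference from the immature Schwann cell list reversed to 0.51; the cause was not tested. The 49 pairs kept their direction under each alternative, and 46 passed without replicate 3, where limma gave all pairs a common SE. Genes differing between libraries numbered 200 at a mean of 1 TPM, 1 at 50 TPM, 19 at a ratio of 1.5, 1 without genes under 200 bases, 0 with at least 100 counts, and 1 to 3 when a library was left out, against 2. The cause of these changes was not tested. Rescaling without ribosomal protein genes multiplied the levels of named genes by a median of 1.11, and leaving out 1 of 3 libraries cannot move a mean by as much as its SD. Depth limits statements on genes near 0.2 TPM, where a library holds about 3 counts for a gene of median length.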

Other observations

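The tests of this part were chosen after the data were seen, and so were the gene families described in it. Of 26 measured Hox genes, which mark position along the body axis, 17 were at 1 TPM or more in each library, with Hoxb9 at 80.8 ± 2.03 TPM, Hoxb7 at 77.1 ± 4.91, Hoxb3 at 40.3 ± 1.54, Hoxc10 at 38.2 ± 1.83 and Hoxc8 at 29.9 ± 2.61 (SD, n = 3). All 7 measured Hoxc genes and 6 of 7 Hoxb genes were at that level, and Hoxb13 had no count. Of 7 Hoxd genes 4 were at that level, led by Hoxd9 at 10.6 ± 0.966 and Hoxd10 at 6.62 ± 0.903. None of the 5 Hoxa genes was, but 4 of them are listed at 2 places, so the Hoxa cluster cannot be judged.

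Families of axon guidance genes differed in level, and no enrichment was tested. All 19 semaphorins were at 1 TPM or more in each library, led by the secreted Sema3b at 517 ± 18.6 TPM, Sema3c at 170 ± 7.66 and Sema3g at 133 ± 2.02. Their receptors included Nrp1 at 178 ± 10.9, Plxnb2 at 158 ± 2.53 and Plxnb3 at 126 ± 2.92. Efnb1 at 392 ± 7.43 was the highest of 7 ephrins, and 8 of 11 Eph receptors were at 1 TPM or more, with Ephb3 and Ephb2 at 80.1 ± 0.572 and 53.3 ± 1.26. Of 7 Slit and Robo genes 5 were at 1 TPM or more, and Robo4, which was not, is listed at 2 places and cannot be judged. Slit2 and Slit3 were at 48.4 ± 2.73 and 33.1 ± 0.325, while the receptors Robo1 and Robo2 were at 9.22 ± 0.358 and 4.02 ± 0.228. Of 9 netrins and netrin receptors 6 were at 1 TPM or more and none reached 10 TPM, with Ntn1 at 8.10 ± 0.359 and the receptor Dcc at 0.009 ± 0.0156. Among the connexins, 5 of 18 were at 1 TPM or more, with Gja1 at 198 ± 3.53, Gjc1 at 71.0 ± 2.46 and the myelin connexin Gjb1 at 12.3 ± 0.849.

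Several widely used genes lay near 0 TPM. Among subunits of 4 complexes that all cells need (ribosome, proteasome, RNA polymerase II and chaperonin), the 7 genes listed at 2 places, including Polr2h with no count and Rps6 at 12.7 ± 2.52 TPM, had a median TPM that was 0.00369 of that of the other subunits. Of these 7 genes, 4 encode ribosomal proteins and 3 encode RNA polymerase II subunits, and none belongs to the proteasome or chaperonin. Doubled gene length can halve a TPM but not lower it to 0.00692 of the other genes' median, as seen for ribosomal protein genes, and low depth is argued against by at least 418 counts expected per library at the median of the same complex. A candidate explanation is that reads matching both places were not counted, although Rpl37a was at 1.52 TPM without being listed at 2 places. No biological explanation was tested, and levels of Col1a2, Hprt1, Ogn and Dkk1 cannot be read from these counts.

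Fibroblast genes were high beside the precursor genes. The scaling by gene length is argued against by the raw counts, whose median percentile among genes with a count was 97.6 for the 13 fibroblast markers listed at 1 place. That 12 of the 13 (92.3%) were at 1 TPM or more in each library, against 78.8% of all genes with a count (1-sided binomial p = 0.203), decides nothing, because only 13 of 13 could have given a p under 0.05 and the cut lies far below the level of most of these markers. The transcription factors Prrx1, Twist2 and Tbx18 were at 109 ± 4.27, 12.9 ± 1.35 and 6.98 ± 0.114 TPM, and Meox1 at 0.176 ± 0.0358. Fibroblast-lineage cells in the cultures and expression of matrix genes by the Schwann cells themselves cannot be told apart, because no library free of fibroblasts was analysed, and the markers' median was 0.803 ± 0.0232 of that of the precursor list.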
